A study of Escherichia coli with 9 samples.

How the data were processed

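Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Escherichia coli K-12 MG1655, the common laboratory strain. Per the labels, cells were crosslinked with formaldehyde, and DNA was sheared to about 200 bp and precipitated either with an antibody against the FLAG epitope or with an antibody against the beta subunit of RNA polymerase (RNAP). The FLAG libraries came from strains in which H-NS or Fis, both abundant proteins that bind and shape the bacterial chromosome, carried a triple FLAG tag. The RNAP libraries came from the wild type and from strains in which hns or fis was disrupted by a kanamycin resistance cassette. The labels name 9 samples in 9 groups, each with 1 library. The Fis library from early-exponential phase was not analysed here, which left 8 libraries.

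Each of the 8 deposited files held a whole-number coverage signal for every position from 1 to 4639675, with no normalization between libraries. The aligner and genome build are not given in the sources used here. From the values, each read had been extended to a length of about 200 bp, since the autocorrelation of the base-to-base change in coverage was lowest at a lag of 200 bp or the next in all 8 libraries. Dividing the summed coverage by 200 gave the depth as read equivalents, which ranged from 5.96 M (Fis) to 17.5 M (RNAP, wild type), M standing for mega. Reads with the same ends could not be separated from independent molecules, so the Poisson intervals given here cover counting error only.

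Positions at 0 in all 8 files (12022 positions) were masked. The chromosome was divided into 200 bp tiles, and the 23122 of 23199 tiles with at least 80% of their positions unmasked were used. The level of a tile was its mean coverage divided by the local background, the median tile within 100 kb on either side in the same library, with the chromosome treated as circular. Scaling to background in this way removes differences in depth and broad differences in DNA copy number along the chromosome. It also means that a change shared by most tiles of a 200 kb stretch would not be seen. For RNAP the local median also reflects RNAP occupancy and is not a neutral floor. In 100 kb windows, the median of unbound tiles in the wild type was 0.301 times the library median from 300001. From 3300001 it was 1.95 times. In the window from 4200001 it was 1.26 in the wild type and 0.598 in the hns mutant, so RNAP ratios depend on it. No input or mock library was used, so a level above background is enrichment relative to the surrounding chromosome and not to unprecipitated DNA.

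A tile was called bound by H-NS or Fis at a level of 2 or more with a neighbouring tile also at 2 or more, and runs of at least 2 bound tiles are called regions. For RNAP, a pseudocount of 0.25 was added to each level. A tile was called higher or lower in a mutant when its ratio to the wild type was at least 2-fold and its level was 1.5 or more in at least 1 of the 2 libraries. Fold values of RNAP include this pseudocount, which understates the change of low tiles. "Rose" and "fell" refer to changes of at least 2-fold by these rules. With 1 library per group there were no replicates and no p-values. Shares are given with exact 95% binomial (Clopper-Pearson) intervals and ratios of reads with 95% Poisson intervals. The binomial intervals of tile shares treat tiles as independent draws. Neighbouring tiles share extended reads and bound tiles lie in runs, so these intervals are too narrow. For the overlap of sets of tiles, 10000 random rotations of the set around the chromosome gave the chance range (middle 95%), which keeps the lengths and spacing of regions.

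The gene table at hand was of assembly ASM584v2, which runs past the last position of the files, so the builds differ. None of its coordinates were used, coordinates were not converted, and tiles and regions took the place of genes as set out beforehand. Gene names are given only for hns, which could be placed by a gap in coverage, and for genes next to hns or fis in the table. Gene lists prepared in advance were not analysed here for the same reason, nor was base composition. Named regions followed a rule fixed before the data were examined. For H-NS and Fis at mid-exponential phase these were the 10 strongest and 10 longest regions. Across phases they were the 10 with the largest and the 10 with the smallest ratio of stationary to early-exponential level. For each RNAP comparison they were the 10 runs of called tiles with the largest change in each direction, of which examples are given.

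The deleted gene was sought by listing stretches of at least 20 bp with coverage of 1 or less in a mutant and 200 or more in the wild type, and the reverse. Because the ratios of both mutants share the wild type library, their correlation was set beside that from 20 simulated pairs of unchanged libraries and beside that from wild type reads split at random between the comparisons.

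The steps were tested on simulated data with Poisson counts over the 23122 tiles. In the simulated H-NS mid-exponential library, 99.9% of tiles raised 3-fold and 100% of those raised 5-fold were called bound, none of those raised 1.5-fold were, and there were 0 other calls. In the simulated hns mutant comparison, 98.5% of 200 tiles changed 3-fold and 100% of those changed 4-fold were recovered. In the simulated fis mutant comparison the corresponding values were 99% and 98.5%. Changes of 1.5-fold gave 0 calls in both, as the rule requires, and no unchanged tile was called. The changed tiles of both comparisons were drawn only from tiles with a wild type level of 1.5 or more. Most H-NS bound tiles lay below that level, where a rise also has to reach 1.5. The recovery given here does not apply to them. The simulated libraries held counting noise only, for H-NS on a smooth background, so other calls were hardly possible. The absence of other calls therefore gives no rate of false calls in the real libraries.

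Alternatives fixed beforehand were a genome-wide background, a 3-fold threshold, 500 bp tiles, thinning to the shallowest library, leaving out RNAP-rich tiles, a pseudocount of 0.05 and no level filter. A wider mask, scaling to equal total coverage, removal of a trend with RNAP level, sets of equal size and splits of RNAP calls and their overlap by wild type level were added after the data had been seen. The wider mask left out tiles with a level under 0.3 in any FLAG library. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.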

Results

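The data comprised 4 H-NS libraries, from early-exponential, mid-exponential, transition to stationary and stationary phase, a Fis library from mid-exponential phase, and 3 RNAP libraries from mid-exponential wild type, fis mutant and hns mutant cells. Each group had 1 library, so no difference below could be set against the spread between replicates. Depth was 9.08 M, 6.17 M, 11 M and 13.8 M read equivalents (M, mega) for H-NS in the order of growth, 5.96 M for Fis, and 17.5 M, 17.4 M and 14.1 M for RNAP in the wild type, the fis mutant and the hns mutant. The median 200 bp tile held between 142 reads (H-NS, mid-exponential) and 301 reads (H-NS, transition). At 142 reads the 95% Poisson interval spans from -15.8% to +17.9% of the value, well inside the 2-fold rule. All coordinates are those of the deposited files, on the single chromosome of the strain.

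The deleted genes were examined first in the RNAP libraries. RNAP coverage of the hns mutant fell to 1 or less over a single stretch of 61 bp, 1291909–1291969, where the wild type stood at 11.9 times background with coverage up to 3325. The fis mutant stood at 4.66 times background there. No other stretch of the chromosome met the rule, and the reverse comparison gave 0. Coverage in the hns mutant dropped to the gap and climbed from it over about 200 bp each, and the flanking maxima lay 462 bp apart, against a length of 414 bp for hns, the gene of H-NS, which lies between galU and tdk. The library labelled as the hns mutant thus lacked a single hns-sized segment, taken here as hns. For fis, a gene of 297 bp between dusB and yhdJ, reads extended by 200 bp from both sides would cover a deletion shorter than 400 bp, and the scan found 0 stretches. The deepest local dip of the fis mutant against the wild type, at position 3409414, had a log2 depth of 2.63 and did not stand apart from the next at 2.52, whereas that in hns was 9.49 against 3.30. The label of the fis mutant was therefore not checked here. The position of the dip was not set against that of fis, since the coordinates of the gene table were not used.

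**Figure D1:**
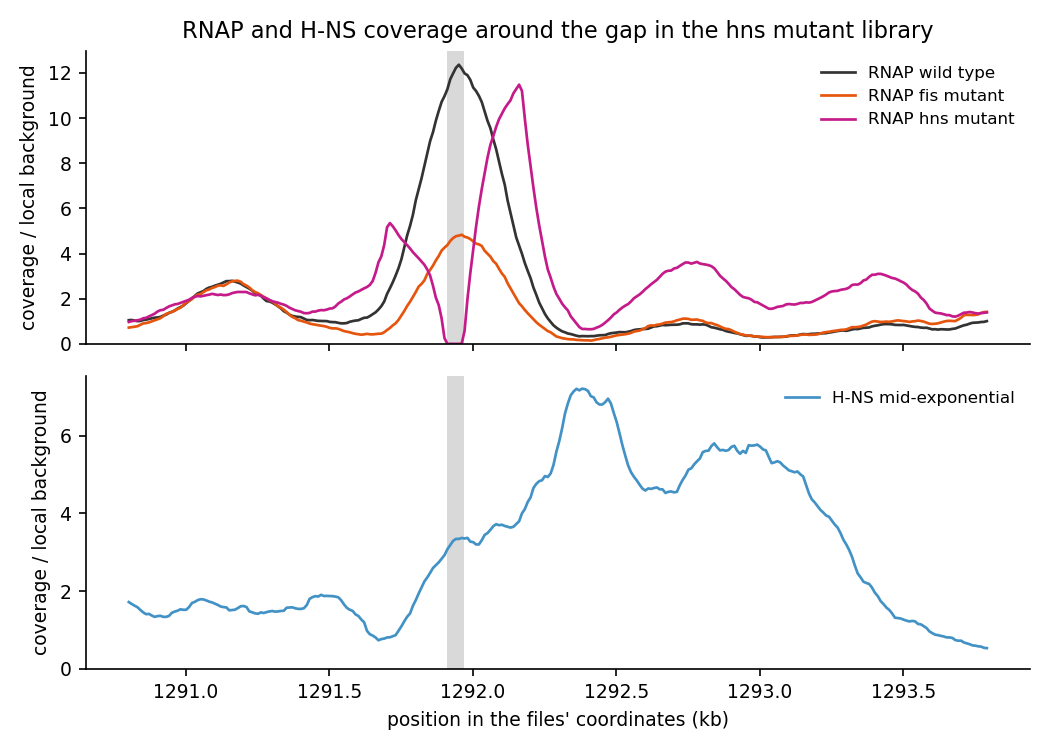
Coverage over local background in 10 bp steps around the gap (grey) for RNAP in the wild type, fis mutant and hns mutant (top) and for H-NS at mid-exponential phase (bottom), against position in kb. RNAP coverage in the hns mutant is 1 or less in the 61 bp gap, where the wild type is at 11.9 times background. The RNAP level is above the wild type in the H-NS bound tiles to the right of the gap. It is also above it in the unbound tiles next to the bound region on either side.

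The hns locus was itself bound by H-NS. A bound region of 1600 bp, 1291801–1293400, held the gap, and its mean H-NS level was 3.14, 4.63, 3.9 and 6.48 from early-exponential to stationary phase. In the 1200 bp of this region from 1292201 on, the RNAP level of each of the 6 tiles was above the wild type in the hns mutant. Tiles without bound H-NS beside it also had more RNAP in the hns mutant, with 0.813 in the wild type and 2.59 in the mutant at 1293401–1293600 and 2.55 and 3.88 at 1291601–1291800. A kanamycin resistance cassette disrupts hns in this strain. Any effect of the cassette on RNAP beside the gap could not be told apart from that of losing H-NS. Within the bound part, at 1292801–1293000, the RNAP level was 0.555 in the wild type, 0.634 in the fis mutant and 2.66 in the hns mutant.

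H-NS, which binds AT-rich DNA and silences many of the genes there, was mapped at 4 growth phases to ask whether its binding changes as cells leave exponential growth. It occupied long stretches of the chromosome at all phases, and the bound set was larger in stationary phase. At early-exponential phase 3071 tiles were bound (13.3% of tiles, 95% interval 12.8 to 13.7), at mid-exponential phase 3642 (15.8%, 15.3 to 16.2), at the transition 3411 (14.8%, 14.3 to 15.2) and at stationary phase 4316 (18.7%, 18.2 to 19.2). These tiles formed 411, 440, 482 and 518 regions, with median lengths of 1200, 1200, 1100 and 1200 bp. The longest regions measured 12.2, 12.4, 12.4 and 14.8 kb. Bound tiles held 44.2% of all coverage at early-exponential phase, 56.6% at mid-exponential phase, 47.4% at the transition and 63.9% at stationary phase.

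Most tiles bound early were bound at the later phases. All 3071 early-exponential tiles were also bound at mid-exponential phase, 2984 of them (97.2%, 96.5 to 97.7) at the transition and 3057 (99.5%, 99.2 to 99.8) at stationary phase, the last against a mean of 18.6% for rotated sets. Of the mid-exponential tiles, 84.3% (83.1 to 85.5) were bound at early-exponential phase, 92.3% (91.3 to 93.1) at the transition and 98.4% (98.0 to 98.8) at stationary phase, an order that follows the sizes of the sets. With the 3071 highest tiles of each library the order was reversed, at 95.7%, 94.8% and 90.6%, and early-exponential and stationary phase shared 89.2%. A core of 2984 tiles was bound at all 4 phases. In the other direction, 1259 tiles were bound at stationary but not at early-exponential phase, 14 at early-exponential but not at stationary phase, and 682 at stationary phase only. The median early-exponential level of the 1259 tiles was 1.49, above the 0.937 of tiles bound at no phase.

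The strongest mid-exponential H-NS region was 4218201–4221200, with a highest tile of 28.6 times background, followed by 1379401–1381800 (25.3) and 3803201–3806200 (23.2). All 10 of the strongest regions had a highest tile of 21.6 or more. Wild type RNAP over these 10 ranged from 0.216 to 1.2 times background. The longest region, 2478401–2490800, measured 12.4 kb with a mean H-NS level of 8.98, and 2101001–2111600 and 2983801–2994400 each measured 10.6 kb, with mean levels of 8.63 and 9.76. RNAP over the 10 longest regions had a median of 0.725 in the wild type.

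**Figure D2:**
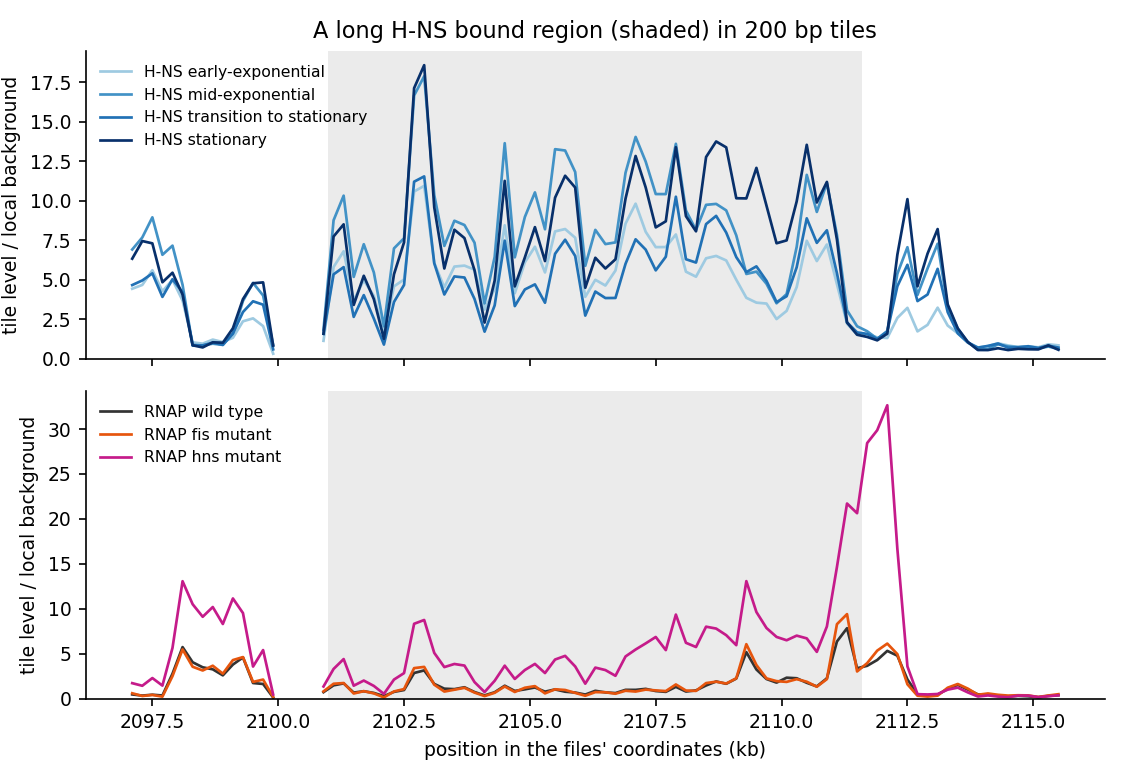
Tile levels over local background along 2101001–2111600 (shaded) and 4 kb on either side, against position in kb, for H-NS at 4 growth phases (top) and RNAP in 3 strains (bottom); a break marks masked tiles. Mean H-NS over the region is 5.69, 8.63, 5.49 and 8.46 from early-exponential to stationary phase, with a few tiles under 2 outside mid-exponential phase, and mean RNAP over it is 1.63 in the wild type, 1.72 in the fis mutant and 5.71 in the hns mutant.

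Between early-exponential and stationary phase, the H-NS level changed unevenly among the 512 regions bound in either. The median ratio of stationary to early-exponential level was 1.82, 192 regions rose at least 2-fold, and 0 fell at least 2-fold. In the 2984 tiles bound at all 4 phases, the median ratio to early-exponential level was 1.46 at mid-exponential, 1.07 at transition and 1.68 at stationary phase. Levels were not corrected for such a shift of a whole library. A 2-fold rise therefore lies close to the common shift, and a 2-fold fall lies far from it. The largest rise was at 2266601–2268600, from 1.03 to 8.70 times background (8.44-fold), with 2.59 and 4.49 at the intermediate phases. Next came 2171601–2173800, from 1.21 to 9.03 (7.46-fold), and 3537601–3538800, from 1.56 to 8.49 (5.43-fold). Wild type RNAP at mid-exponential phase was 5.36, 89.99 and 0.685 times background at these 3. Of the 10 largest rises 7 had an RNAP level of 2 or more, against 0 of the 10 lowest ratios. At the other end, 1891401–1891800 had levels of 2.5 and 2.22 and 1524601–1526000 had 4.56 and 4.52, and the 10 lowest ratios ran from 0.887 to 1.07. These low ratios depended on the local background: with a genome-wide background 8 of the 10 moved by more than 1.5-fold, to 1.58 at 1891401 and 2.07 at 1524601, and all 10 lay between 1.07 and 2.2. The 10 largest rises then ranged from 2.66 to 11.4-fold, and 260 of the 512 regions rose while 0 fell at least 2-fold. Ratios under 1 were found in 29 of the 512 regions with this background, the lowest at 0.711, against 3 regions with the local background. Over all regions, 59 of the 192 that rose (30.7%) had a mid-exponential wild type RNAP level of 2 or more, against 42 of the other 320 (13.1%). For single tiles the share was 28.7% over all tiles and 12.3% over tiles bound by H-NS at mid-exponential phase. Most of the 10 largest rises were under a level of 2 at early-exponential phase. These shares therefore do not separate a gain at RNAP-rich DNA from low RNAP in DNA that was already bound.

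The background between bound regions also changed in shape with growth phase. Between tiles from 3.8 to 3.9 Mb and those from 1.6 to 1.7 Mb, the ratio of median unbound coverage was 2.31 at early-exponential, 1.32 at mid-exponential, 0.935 at transition and 0.687 at stationary phase in the H-NS libraries. In the Fis library it was 1.92, so the 2 mid-exponential FLAG libraries differed in this gradient. Levels are divided by the local background, so ratios of stationary to early-exponential H-NS level depend on whether this gradient is taken out. The ratio was 0.991 with the local and 2.07 with the genome-wide background at 1524601–1526000. At 3887801–3889200 it went the other way, from 4.18 to 2.66.

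**Figure D3:**
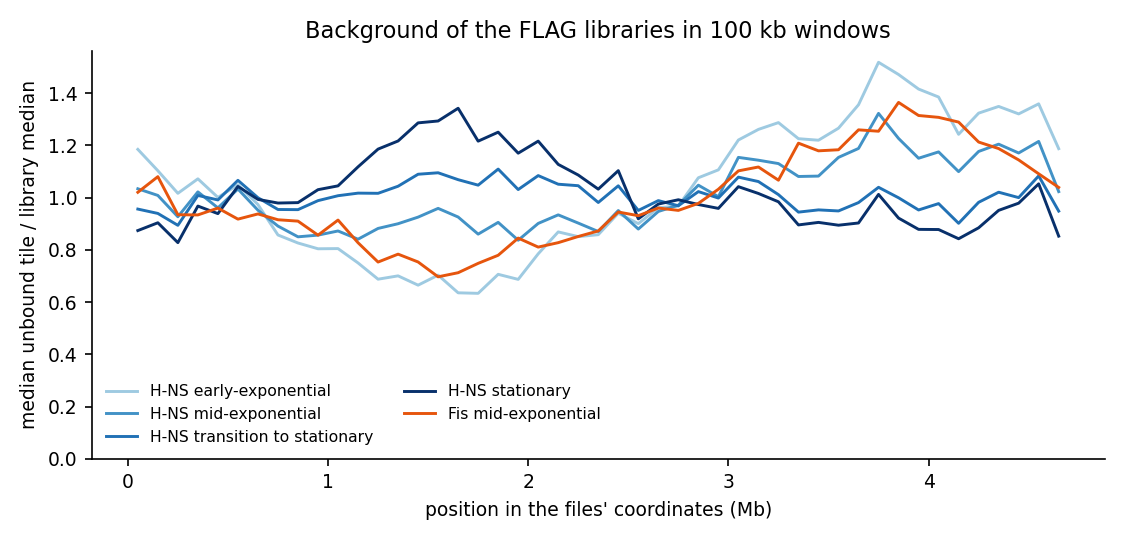
Median coverage of unbound tiles in 100 kb windows, divided by the library's own median, against position in Mb for the 5 FLAG libraries. The ratio of 3.8 to 1.6 Mb runs from 2.31 at early-exponential to 0.687 at stationary phase.

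Fis, a protein abundant in fast-growing cells, bound shorter sites. At mid-exponential phase 732 tiles (3.17%, 2.94 to 3.40) were bound in 321 regions of median length 400 bp, the longest of which measured 1200 bp. These tiles held 9.39% of all coverage. The strongest region was 3537801–3538400, with a highest tile of 17.0 times background, followed by 2561201–2561600 (12.9) and 4099201–4099800 (11.2). Wild type RNAP at these 3 was 0.609, 0.288 and 0.173, while 2945201–2945600, the 10th strongest, had 13.6. The median level of Fis bound tiles was 2.88, and at a 3-fold threshold 201 of them were left.

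Fis and H-NS were compared to ask whether they share sites. At mid-exponential phase 121 of 732 Fis tiles were also bound by H-NS (16.5%, 13.9 to 19.4), within the 12.0 to 19.5% of rotated sets. With stationary H-NS tiles the share was 22.5% (19.6 to 25.7), also within the range of rotated sets (14.8 to 22.7%), and with early-exponential tiles it was 9.43% (7.41 to 11.8), just under theirs (9.84 to 16.7%). Among the strongest Fis regions, 344201–344600 carried both proteins (Fis 7.68, H-NS 6.24), and 2561201–2561600 carried Fis alone (10.5, with H-NS at 0.347). At 3537801–3538400 H-NS stood at 1.47 at early-exponential and 10.2 at stationary phase.

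The proteins differed in the RNAP of the tiles they bound in wild type cells. H-NS bound tiles were poor in RNAP, with a median level of 0.441 against 1.16 in unbound tiles, and 12.3% (11.2 to 13.4) of them had an RNAP level of 2 or more, against 25.2 to 32.2% for rotated sets. Fis bound tiles were richer than the rest, with a median of 1.65 against 0.986, and 43.9% (40.2 to 47.5) of them had a level of 2 or more, against 24.3 to 33.2% for rotated sets.

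The hns mutant was compared with the wild type to find where RNAP changes without H-NS. RNAP rose in 2026 tiles and fell in 2094 of the 10704 that passed the level filter. H-NS bound tiles made up 36.8% (34.7 to 38.9) of the tiles that rose, against 12.0 to 19.6% for rotated sets, and 4.49% (3.64 to 5.47) of those that fell. The level filter shapes these shares, since a tile could fall only from a wild type level of 1.5 or more, which 600 of the 3642 bound tiles had. Among tiles at that level, RNAP rose in 23.8% (20.5 to 27.4) of bound and 8.21% (7.62 to 8.83) of unbound tiles and fell in 15.7% (12.8 to 18.8) and 25.1% (24.1 to 26.0), with median log2 ratios of 0.13 and -0.34. Among tiles below it, which had to reach 1.5 in the mutant, RNAP rose in 19.8% (18.4 to 21.3) of bound and 5.44% (5.03 to 5.87) of unbound tiles. The median log2 ratio was 0.64 over the 3642 H-NS bound tiles, -0.17 over unbound tiles and -0.07 over all tiles. In level, the median of bound tiles was 0.441 in the wild type and 0.987 in the hns mutant, where unbound tiles stood at 1.00. At the same bound tiles the fis mutant had a median log2 ratio of -0.17. With libraries scaled to equal total coverage, tiles that rose made up 59.6% of changed tiles in place of 49.2%.

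The ratio of hns mutant to wild type was larger at stronger H-NS binding, through the wild type level rather than the level reached. In 4 equal groups of bound tiles, from the lowest to the highest H-NS level, RNAP rose in 12.4% (10.3 to 14.7), 16.2% (13.8 to 18.7), 25.6% (22.8 to 28.6) and 27.7% (24.8 to 30.7) of tiles. The median RNAP level of these groups was 0.776, 0.495, 0.369 and 0.296 in the wild type and 1.02, 0.913, 1.02 and 0.962 in the hns mutant. By length, it rose in 7.22% (4.77 to 10.4) of bound tiles in regions of 400 to 800 bp, 18.5% (16.4 to 20.7) in those of 1000 to 1800 bp and 24.2% (22.3 to 26.2) in those of 2000 bp or more. Of the 440 regions, 185 (42.0%, 37.4 to 46.8) held at least 1 tile in which RNAP rose, and in 55 (12.5%) at least as many tiles rose as did not. The latter share was 7.32%, 14.5% and 14.5% in the 3 classes of length. Tiles bound at stationary phase only, which H-NS did not occupy by the rule at the phase of the RNAP libraries, rose in 6.60% (4.85 to 8.73) of cases, against 6.54% (6.19 to 6.90) for tiles bound at no phase.

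**Figure D4:**
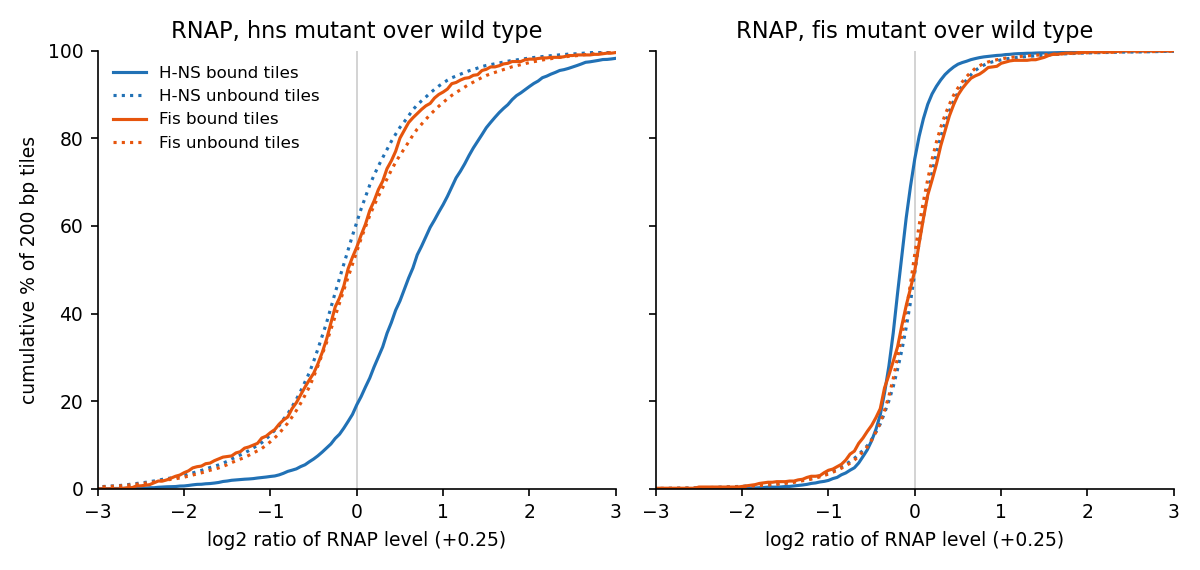
Cumulative percentage of 200 bp tiles against the log2 ratio of RNAP level in the hns mutant (left) and the fis mutant (right) over the wild type, for tiles bound (solid) and not bound (dotted) by H-NS or Fis at mid-exponential phase. H-NS bound tiles are shifted to a median of 0.64 in the hns mutant and lie at -0.17 in the fis mutant, while Fis bound tiles have a median of 0.00 in the fis mutant.

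All 10 regions with the largest RNAP rises in the hns mutant held an H-NS bound tile, though over the 5000 bp of 446001–451000 the mean H-NS level was 1.33. At 2795801–2796800 the RNAP level was 0.434 in the wild type, 0.388 in the fis mutant and 6.84 in the hns mutant (10.4-fold; ratio of levels 15.8, Poisson interval 14.4 to 17.3), with an H-NS level of 9.47. The rise was 10.4-fold at 577401–578200 and 10.3-fold at 3665201–3666000. At 331001–333000, 2000 bp long, RNAP went from 1.37 to 15.8. Among the longest H-NS regions, 3651201–3657200 had mean RNAP levels of 2.76 in the wild type and 14.4 in the hns mutant, whereas 2983801–2994400 had 0.219 and 0.542. Over the whole chromosome, 164 of 341 regions of raised RNAP (48.1%, 42.7 to 53.5) held an H-NS bound tile. Within 1 kb of an H-NS bound tile lay 56.9% (51.4 to 62.2), against 29.9 to 41.3% for rotated sets.

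Of the 326 regions in which RNAP fell in the hns mutant, 32 (9.82%, 6.81 to 13.6) held an H-NS bound tile, a share that the level filter keeps low. Within 1 kb of an H-NS bound tile lay 22.4% (18.0 to 27.3), against 30.7 to 41.7% for rotated sets. Falls of 11.6-fold were found at 1490201–1493000, from 48.1 times background to 3.93, and at 970801–972400, from 9.83 to 0.621, where the fis mutant stood at 9.72. With a genome-wide background the fall was 7.32-fold at the former and 12.6-fold at the latter. Over the 7800 bp of 2347401–2355200 it went from 34.9 to 4.70, with 23.8 in the fis mutant.

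Fewer tiles changed in the fis mutant. RNAP rose in 425 tiles and fell in 679 of the 9694 that passed the level filter, so that tiles that rose made up 38.5% of changed tiles, or 48.5% with libraries scaled to equal total coverage. The correlation of RNAP level with the wild type across tiles, which are not independent replicates, was 0.94, against 0.77 for the hns mutant. The tiles that changed were no richer in Fis binding than others. Of the 1104 changed tiles, 46 were Fis bound (4.17%, 3.07 to 5.52), against 4.31% (3.92 to 4.74) of all that passed the filter; the share was 4.71% (2.90 to 7.17) for tiles that rose and 3.83% (2.52 to 5.56) for those that fell. At the 732 Fis bound tiles the median log2 ratio was 0.00. Within 1 kb of a Fis bound tile lay 25.5% (14.7 to 39.0) of the 55 raised regions and 26.5% (18.7 to 35.7) of the 113 lowered regions, both within the range of rotated sets.

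The largest fis mutant rise covered neighbouring regions at 3268001–3273000, where RNAP went from 1.15 to 9.82 (7.19-fold), and 3273201–3275400, from 1.6 to 13 (7.16-fold); the hns mutant stood at 1.10 and 1.11 there. Also raised were 2915601–2920400, from 0.875 to 7.19, and 940001–944600, from 1.5 to 7.31. The strongest fall was at 3215001–3217400, from 19.4 to 1.67 (10.3-fold), a region with a Fis bound tile. It was followed by 3843201–3844200 (10.8 to 1.53) and 1242601–1244000 (10.9 to 1.66). Of the 10 largest changes in each direction, 3 that rose and 3 that fell held a Fis bound tile, while over all regions it was 10 of 55 (18.2%) and 11 of 113 (9.73%).

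The mutants were also compared with each other. Across tiles the log2 ratios of the hns and fis mutants correlated with a Pearson r of 0.21 (Spearman 0.18) and a covariance of 0.0994. Simulated unchanged libraries, which share the wild type, gave a mean r of 0.47 and a covariance of 0.00481, and splitting the wild type reads between the comparisons gave 0.19 and 0.0936. Of the 8578 tiles with a wild type level of 1.5 or more, which neither mutant decides, RNAP fell in both mutants in 468, against 166 for independent lists, and rose in both in 27, against 21.2. Selecting on the wild type level, which both ratios share, can favour joint falls over joint rises. Over all 9054 tiles tested in both, the independent number for falls was 157, and RNAP rose in both in 48, against 28.2. The region from 1490201 was among the strongest falls in both, at 48.1 in the wild type, 3.93 in the hns mutant and 8.13 in the fis mutant. Both ratios rest on the same wild type culture, so part of the excess may come from that library.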

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

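Depth had little effect on the bound sets and RNAP calls, since thinning to the shallowest library kept all counts and shares that were run within their ranges, while the spread between libraries of a group was not measured. No change called by the 2-fold rule turned its direction in the named regions, of whose values 147 stayed within 1.5-fold and 13 moved further, 12 of these with a genome-wide background. Ratios of stationary to early-exponential H-NS near 1 did cross it, at 1891401 from a log2 of -0.17 to 0.66, at 1462601 from -0.02 to 0.94 and at 1524601 from -0.01 to 1.05 with that background, and at 1462601 to 0.02 with thinning. The causes of the shifts given here were not tested, apart from those that follow by construction. A stricter threshold, a removed filter or leaving out RNAP-rich tiles changes the number of calls in this way. With 500 bp tiles a bound tile still needed a bound neighbour, which works against short regions such as those of Fis (median 400 bp). With a genome-wide background, the shares of mid-exponential H-NS tiles bound at early-exponential, transition and stationary phase were 81.3%, 93.4% and 97.1%, and the correlation between the mutants was 0.19. At a 3-fold threshold these shares were 78.0%, 83.6% and 96.2%. There, 42 H-NS regions rose from early-exponential to stationary phase, 201 Fis tiles were bound, RNAP rose in 1035 and fell in 1101 tiles of the hns mutant and rose in 193 and fell in 243 of the fis mutant, 41.9% of tiles that rose in the hns mutant were H-NS bound with a median log2 ratio of 0.76 over bound tiles, and 1.83% of tiles changed in the fis mutant were Fis bound. With 500 bp tiles 121 H-NS regions rose, the transition share was 93.7%, Fis bound the length of 260 tiles of 200 bp (104 tiles of 500 bp), and the bound shares of RNAP changes were 39.5% for H-NS and 1.68% for Fis. Leaving out RNAP-rich tiles gave an early-exponential share of 86.6%, 411 Fis tiles, and 22.6% of these H-NS bound. H-NS bound tiles are poor in RNAP, so leaving out RNAP-rich tiles also raises the H-NS bound share of all tiles that remain. No chance range is given for the 22.6%. A pseudocount of 0.05 gave a correlation of 0.17 and a median log2 ratio of 0.88 over H-NS bound tiles, and without the level filter 47.1% of tiles that rose in the hns mutant were H-NS bound. Among alternatives chosen after seeing the data, the wider mask gave a transition share of 93.5%. Equal total coverage gave 34.0% of raised tiles H-NS bound and a median of 0.82, with the median over all tiles moving across 0, from -0.07 to 0.06. Sets of the same number of top tiles gave 95.7%, 94.8% and 90.6% for the early-exponential, transition and stationary shares. The medians of the gene lists were not run, since the lists could not be placed in the coordinates of the files, and for the gap in hns, which is read per base, only the genome-wide background gave a value.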

Other observations

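Fis and H-NS levels were also read at the most RNAP-rich DNA. In the 232 tiles that make up the top 1% of wild type RNAP, the median Fis level was 1.08 and 11 tiles were Fis bound. The Fis library had 32024 positions at 0 and the wild type RNAP library 20663. Tiles with RNAP reads but few FLAG reads for this reason would count as unbound. No values with the wider mask are given for these tiles. H-NS bound 8 of them at early-exponential, 11 at mid-exponential, 17 at transition and 35 at stationary phase, with median levels from 0.903 to 1.02. Of the 732 Fis bound tiles, 36.6% had a wild type RNAP level under background. Of the 1259 tiles bound by H-NS at stationary but not early-exponential phase, 59.2% (56.4 to 61.9) lay on the side of the chromosome around the low point of the early-exponential background, which held 50.0% of all tiles and 54.3% (52.5 to 56.1) of tiles bound at all 4 phases.

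Thinning was planned before the data were examined. The other tests in the following paragraphs were chosen after the results had been seen, and only for the removal of the trend with RNAP level was the outcome predicted before it was computed.

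H-NS bound 4316 tiles at stationary and 3071 at early-exponential phase. Depth does not account for this, since thinning all libraries to the shallowest left a ratio of 1.4. A single stronger enrichment factor in the stationary library falls short as the whole cause: scaling the early-exponential levels above background by the factor of 1.88 seen in the core tiles gave 3739 bound tiles. It could still be part of the cause, because 512 of the 668 tiles that this scaling adds are bound at stationary phase and cannot be told apart from a change in binding with 1 library per phase. The other 156 are not bound there, and 747 stationary tiles are not reached by the scaling; no biological explanation was tested for these.

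RNAP was higher in the hns mutant at H-NS bound tiles, with a median log2 ratio of 0.64. The low wild type level of these tiles is argued against by unbound tiles matched on wild type RNAP, of which 10000 random lists reached a highest median of -0.069. An upward bias of these tiles common to mutant libraries is argued against by the fis mutant, with a median of -0.17 at the same tiles. That median lay below those of all 10000 matched unbound lists for the fis mutant, whose mean was -0.011. H-NS bound tiles thus differed as a class between libraries in which hns was not disrupted. A base composition bias of the hns mutant library may contribute and stays open, since no sequence was at hand to match the tiles, of which 20.5% passed the rule for a rise. Loss of silencing without H-NS, the difference the strains were made for, is also a hypothesis and was not tested apart from that bias.

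RNAP fell in both mutants in 468 tiles, 2.98 times the number for independent lists among tiles tested in both. The excess was 2.82 times among tiles with a wild type level of 1.5 or more and 6.33 times at a 3-fold threshold. Without the level filter it was 5.96 times, mainly through the larger pool. There, 507 tiles fell in both, against 85 for independent lists once all 23122 tiles were counted. Independent lists share no wild type library, as these ratios do, so they give a reference and not a chance value. Counting noise in the shared wild type reads is too small, as the observed covariance was 20.7 times the simulated one. A wild type library with more contrast between high and low tiles is argued against as the whole cause, since removing the trend with RNAP level left the excess at 2.93 times. A deviation of the single wild type culture or library could give the same picture and cannot be told apart from an effect common to both mutants without a second wild type library.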
